A study of Solanum lycopersicum and Solanum tuberosum and Capsicum annuum and Nicotiana tabacum with 10 samples.

How the data were processed

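Leaf RNA of 6 plants of the nightshade family was compared on 2-colour microarrays spotted with clones. On each of the 10 arrays, RNA of tomato, pepper, tobacco, Nicotiana benthamiana or petunia, labelled with Cy3, was hybridised together with potato RNA labelled with Cy5, per the labels. Each of the 5 species other than potato was on 2 arrays, numbered 1 and 2 in the labels. Plants had been kept at 25 °C with 16 h of light and 8 h of darkness, and mature leaves had been collected at 4 to 6 weeks, per the labels' protocols. The labels name an RNA column kit in one field and phenol or Trizol extraction in another, so the extraction method stayed open.

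Values were analysed as deposited: 1 log2 ratio per spot and array, already normalised by the authors. The submitters' processing notes name limma, with no version or role. Background correction, the normalisation method, the rule that left spots without a value and the direction of the ratio are not given in the sources used here. The log base was settled from the values: 100.0% of the negative values lay within 0.002 of the log2 of a ratio in whole hundredths, where 16.9% would by chance and 17.7% lay as close to the corresponding natural logs. The ratios had thus been rounded to steps of 0.01 before logs were taken, and the lowest value, -6.643, is the log2 of the smallest such ratio and occurred in 23 cells. Sizes of strongly negative values are therefore coarse.

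The direction of the deposited ratio was not settled. Neither the dyes nor the order of names in the labels says which RNA is the numerator, so signs are given as deposited, on a positive and a negative side, and no value is read as higher or lower in potato. All 10 arrays had the same dye orientation and correlated positively, the lowest r between any pair being 0.648, so they were taken to run the same way. No dye-swapped array and no array of potato against potato was analysed here. A gene-specific dye effect would therefore appear as a shift of all 5 species against potato. It cancels in comparisons between species.

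The value table held 32448 spots, of which 10907 had no value on any array and 12072 had a value on all 10. Every column of values was used. A platform annotation paired 1810 spots (5.58%) with genes, as 905 clones with 2 spots each; the other 30638 spots were unnamed here. Of these clones, 815 had 1 gene symbol and 90 had several. Of the 815, 658 carried only a placeholder symbol (339 symbols), and 157 carried a gene name, for 91 named genes. No gene was named from a clone with several. The 2 spots of a clone were averaged where the annotation identified them, which gave 31543 features, 11569 of them with a value on all 10 arrays. The 2 spots of the same clone correlated with r = 0.985 over 852 named clones. The regular layout of the array pairs unnamed spots in the same way, with r = 0.974 over 9502 pairs, so most unnamed clones enter the counts below as 2 features. Counts with all clones averaged by layout (17088 features) were added after this was seen. Control spots were not marked and could not be left out.

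The number of values per array ran from 16636 to 19866, and array medians ran from 0 to 0.029 log2. The number of arrays limits the precision: with 2 arrays per species, the median standard error of a species mean was 0.193 log2 for tomato. For Nicotiana benthamiana it was 0.194, since the fit estimates 1 spread per feature from all species. The difference between the 2 arrays of a species had an SD over spots of 0.380 in tomato and 0.617 in Nicotiana benthamiana. Standard errors of species means thus tend to be too large for tomato and too small for Nicotiana benthamiana, and so do their p-values. The labels do not say whether the 2 arrays of a species came from separate plants, so p-values measure only the spread between these samples, which may be technical.

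Linear models were fitted to all 10 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per species and empirical Bayes moderation (prior SD 0.276 log2, 4.35 prior degrees of freedom, 5 residual degrees of freedom for a feature with all values). Standard errors of contrasts were computed from each feature's own pattern of missing values. Each species against potato was tested as its mean against 0, where both arrays had a value. The equal-weight mean of the 5 species was tested against 0 for features on all 10 arrays. The 5 species were compared with each other by the moderated F test, each species by its mean minus the mean of the other 4, and tobacco directly with Nicotiana benthamiana. These comparisons between species needed a value on at least 1 array of each species compared, so 20.4% of the features past the threshold in the F test had a species with 1 array, which is assumed to vary like the others. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Correlations were given without a test. The spread of each species' 2 arrays against the 8 others was tested by exact permutation, a test chosen after the values had been seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

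The fit was tested on simulated data with 200 features changed by 1 or 2 log2 units in each species. Of features changed by 1 log2, 45% were recovered for tomato, 57% for pepper, 44% for tobacco, 41% for Nicotiana benthamiana and 49% for petunia. At 2 log2 these shares were 87%, 88%, 89%, 93% and 90%. Unchanged features made up 5.04%, 3.33%, 8.28%, 2.90% and 5.44% of the calls. The simulated noise was independent between arrays, without a potato RNA shared by arrays. In the data far more features passed, 8462 of 17428 in tomato, which eases the adjusted threshold: the smallest tomato ratio past it was 0.389 log2. These shares therefore do not carry over to the counts below.

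The arrays numbered 1 shared 1 potato RNA and the arrays numbered 2 shared another, per the labels' source names, so the numbers pair the arrays. Deviations of same-numbered arrays from their species means correlated in all 10 pairs of species, with r from 0.249 to 0.613 and a median of 0.573. The main model had no block for the number, and the fit with this block was computed beside it. Against potato the block takes the difference between the 2 potato RNAs out of the error although the mean still carries it. Blocked p-values there are therefore too small. Without the block, the mean over all species treated its 10 arrays as independent, although same-numbered arrays share a potato RNA. Its standard errors and p-values therefore tend to be too small as well. Between species the potato RNA cancels where every species compared has values on both arrays. There the main model leaves the difference between the 2 potato RNAs in the error, so its p-values tend to be too large. The blocked fit follows the pairing, which the main counts between species ignore. Where a species has a value on 1 array, its mean carries 1 potato RNA, which does not cancel without the block. Of the tomato calls against the other 4, 22.9% had such a species.

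Before the data were examined, the comparisons, the alternatives and the rule for naming genes were fixed. The rule named, for each species and for the mean of 5 against potato, up to 6 genes per side with the largest log2 ratios past the threshold and the same sign on all arrays of the comparison, and for each species against the other 4 up to 3 genes per side. A gene was represented by its clone with the smallest p-value, which raises counts of named genes past the threshold where genes have several clones. Clones past the threshold on the opposite side to the named clone in the same species are pointed out. It named 36 genes. Genes for tubulin, actin, elongation factor 1-alpha and ubiquitin were to be described as a group, but none of the 91 names was one of them. Also fixed were 31 lists of genes as word patterns for gene descriptions, to be tested with camera and fry. The annotation gave symbols without descriptions; 1 symbol matched, and none of the lists reached the minimum of 5 members. List tests could therefore not be run, and neither could their alternatives with the block, with an estimated correlation or with median-centred arrays. Genes were instead placed in the lists by protein name after their values had been seen, for description only.

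Alternatives were the block, median-centring, scaling to the same median absolute deviation, features with all 10 values, spots kept separate, robust moderation, a minimum of 1 log2 (or adjusted p under 0.01 for the F test), and leaving out each array in turn. For correlations they were Spearman's measure and centring each array number. Added after the data were seen were averaging by layout and the same settings for 2 later results: the count of features past the threshold on the same side in all 5 species, and differences between 2 species in genes that lay on opposite sides. All comparisons against potato share the 2 potato RNAs. Chance agreement between them was simulated 20 times with no species effect and the 2 potato RNAs could not be split further.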

Results

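Gene expression in mature leaves of tomato, pepper, tobacco, Nicotiana benthamiana and petunia was measured against potato leaves on 10 arrays of spotted clones, 2 for each species. The design asks in which genes potato leaves differ from those of its relatives, and in which genes the relatives differ from each other. Diverged sequences might bind the spotted clones less well, to a different degree in each species. A ratio may therefore mix transcript level with binding, which does not cancel between species. The 2 were not separated here, so differences below are differences in ratio. Values are deposited log2 ratios of a species and potato, averaged over 2 arrays (n = 2) unless 1 array is stated, with the standard error of the limma fit. Signs are as deposited: which RNA is the numerator was not settled, so positive and negative name sides of the ratio only. Tomato had 19866 and 18878 measured spots on its arrays 1 and 2, pepper 16636 and 18644, and tobacco 17580 and 18841. Nicotiana benthamiana had 17613 and 18332, and petunia 16987 and 19397. Values of the 2 arrays of a species correlated across spots with r = 0.935 in tomato, 0.888 in pepper, 0.905 in tobacco, 0.868 in Nicotiana benthamiana and 0.894 in petunia. Between 1.51% and 2.35% of their shared values were identical, so no pair was the same array deposited again.

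**Figure D1:**
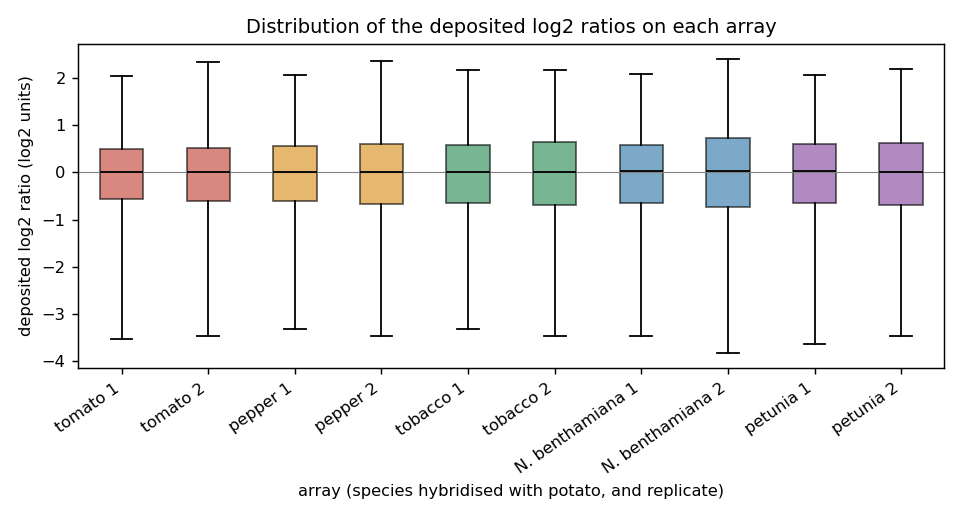
Deposited log2 ratios (vertical axis, log2 units) on each of the 10 arrays; boxes span the quartiles, lines mark medians and whiskers reach percentiles 1 and 99 over spots. Medians lie between 0 and 0.029, and the tomato boxes have the smallest mean height, 1.09 log2.

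GBSS, the granule-bound starch synthase that makes amylose, lay furthest on the positive side among named genes measured on all 10 arrays when the 5 species were averaged, at 2.37 log2 (SE 0.086, 5.18-fold, adjusted p = 1.56e-08, positive on 10 of 10 arrays). Other genes on that side were the methionine synthase gene MS at 1.55 (SE 0.073, adjusted p = 6.97e-08), the flavonol synthase gene FLS at 1.43, HXKRP1 at 1.28, the alternative oxidase gene AOX at 1.16 and LPD2, a dihydrolipoamide dehydrogenase, at 1.15. On the negative side, NAC2, a NAC transcription factor, stood at -3.11 log2 (SE 0.11, 8.64-fold, adjusted p = 1.20e-08, negative on 10 of 10 arrays). The pathogenesis-related gene PR1B followed at -2.53, SRE1A at -2.36, the WRKY transcription factor STWRKY8 at -1.998, SI1 at -1.68 and PHA2, a plasma membrane proton pump, at -1.64. Each of these 12 genes had the same sign on all 10 arrays, as the rule for naming them required. Their SEs and p-values treat the 10 arrays as independent. They tend to be too small, because the arrays share 2 potato RNAs. Clones of FLS and PHA2 differed. An FLS clone without a value on 2 arrays, not tested here, averaged -5.53 and was negative on 8 of 8 arrays, near the limit set by the rounding of the ratios. Another FLS clone gave -0.04 (not past the threshold), and 1 of the 4 PHA2 clones was positive in petunia at 0.70. On the negative side, 3 of 3 PHA2 clones tested passed in tomato. In pepper, tobacco, Nicotiana benthamiana and petunia only 1 of 4 did in each.

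Over all features, 9245 of 11569 (79.9%) passed the threshold for the mean of 5 species, 4472 on the positive and 4773 on the negative side, and 2981 of them lay at least 1 log2 from 0, 1108 on the positive and 1873 on the negative side. With clones averaged by layout, 6502 of 8001 passed. Both counts may be too high, since the test of this mean treats arrays that share 2 potato RNAs as independent. Named genes were more often negative: 41 of the 65 past the threshold, among 74 tested, against 24 positive. In each of the 5 species separately, 2750 of the 11569 features (23.8%) passed on 1 common side, 1129 positive and 1621 negative; independent lists of the same sizes would share 46.1. Simulations without a species effect gave 0, but with a mean of 0.05 calls per species they left almost nothing to overlap. Without tomato array 2 this count was 1649, of which 471 were positive and 1178 negative. The positive side also fell to 683 without tomato array 1 and 741 without pepper array 2, beside 1215 and 1288 negative. Species profiles correlated across features with a mean r of 0.808, and 0.498 in the simulations; the covariances were 0.949 and 0.0315. Because all arrays share 2 potato RNAs that could not be split, part of the excess may come from these shared samples. A gene-specific dye effect would also put all 5 species on 1 common side, as no dye-swapped array was analysed. The excess over independent lists therefore does not by itself show that potato leaves differ. Median-centring turned the balance of sides in 4 species to negative: 3923 positive and 4140 negative in pepper, 4332 and 4572 in tobacco, 4141 and 4697 in Nicotiana benthamiana, and 4216 and 4671 in petunia.

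In tomato, GBSS was again on the positive side at 2.32 log2 (SE 0.19, 4.98-fold, adjusted p = 3.03e-05). PPO, a polyphenol oxidase of the browning reaction, reached 2.27 (SE 0.21, adjusted p = 5.31e-05) and HPL, a hydroperoxide lyase of oxylipin metabolism, 2.11 (SE 0.15, adjusted p = 2.69e-05). LPD2 stood at 2.05, the D-type cyclin gene CYCD3.3 at 1.86 and STP-1 at 1.78. On the negative side, NAC2 stood at -3.56 (SE 0.24, 11.8-fold, adjusted p = 1.05e-05), followed by STWRKY8 at -2.30, the dehydroascorbate reductase gene DHAR at -2.18, STUGE51 at -2.06, PR1B at -1.91 and SRE1A at -1.85. DHAR was split between its clones, another of which was positive in tomato at 1.92. Of 86 named genes tested, 52 passed, 23 positive and 29 negative. Over all features 8462 of 17428 passed (4070 positive, 4392 negative), 4118 of them at 1 log2 or more (1666 positive, 2452 negative). Averaging clones by layout left 5164 of 10144, and the count was 4311 without tomato array 1 (1977 positive, 2334 negative) and 3706 without tomato array 2 (1429 and 2277).

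Pepper had POTPRO1 on the positive side at 2.46 log2 (SE 0.20, 5.50-fold, adjusted p = 4.57e-05), then CO, a CONSTANS-type photoperiod regulator, at 2.13 (SE 0.32, adjusted p = 5.74e-04). STP-1 stood at 1.82, MS at 1.69, STUGE51 at 1.62 and R1, the alpha-glucan water dikinase that phosphorylates starch, at 1.58. A clone of FLS gave -5.89, close to the limit set by the rounding of the ratios, while a second FLS clone was positive at 1.38. PR1B stood at -2.84 (SE 0.21, 7.18-fold, adjusted p = 1.48e-05), NAC2 at -2.82 and VPE2, a vacuolar processing enzyme, at -2.37. The photosystem II gene PSBR stood at -2.29 and SI1 at -2.12. The other VPE2 clone was positive in pepper at 0.50. Of 83 named genes tested, 59 passed, 31 positive and 28 negative. In all, 8108 of 15095 features passed (4120 positive, 3988 negative), 4033 of them at 1 log2 or more (1737 positive, 2296 negative). By layout 5136 of 9255 passed, and 4895 features did so without pepper array 2 (2258 positive, 2637 negative).

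In tobacco, GBSS reached 3.70 log2 (SE 0.19, 13.03-fold, adjusted p = 3.30e-06). HXKRP1 stood at 1.73 (SE 0.14, adjusted p = 2.36e-05), AOX at 1.67, CO at 1.55, the transketolase gene TK at 1.54 and the gibberellin 2-oxidase gene GA2OX1 at 1.32. CO had an adjusted p of 0.0528 without tobacco array 1 and GA2OX1 one of 0.0716 without tobacco array 2. The clones of FLS and PR1B with the smallest p both gave -5.89, near the rounding limit; a second PR1B clone gave -2.63, while a second FLS clone was positive at 1.37. MIP2 stood at -3.45 (SE 0.17, 10.95-fold, adjusted p = 4.65e-06), NAC2 at -3.22, SRE1A at -2.70 and SI1 at -2.56. Named genes leaned to the negative side, 39 against 21 positive among the 60 of 83 that passed. Over all features the sides were nearly even, 4530 positive and 4426 negative of 8956 past the threshold among 15844, with 4711 at 1 log2 or more (2138 positive, 2573 negative). Averaging by layout gave 5569 of 9626, and 5345 features passed without tobacco array 2 (2568 positive, 2777 negative).

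Nicotiana benthamiana had GBSS at 2.14 log2 (SE 0.19, 4.41-fold, adjusted p = 3.02e-05), FLS at 1.85 (SE 0.36, adjusted p = 1.89e-03) and MS at 1.74 (SE 0.16, adjusted p = 3.72e-05) on the positive side. HXKRP1 followed at 1.52, HPL at 1.37 and LPD2 at 1.35. PR1B stood at -2.92 (SE 0.21, 7.59-fold, adjusted p = 8.43e-06). The catalase gene CAT1 stood at -2.59, NAC2 at -2.59, SRE1A at -2.57, STWRKY8 at -2.47 and STUGE51 at -2.28. CAT1 was split, with another clone positive at 0.78. Clones of FLS and PR1B with a value on 1 array of this species, not tested here, both read -5.64, near the rounding limit, and MIP2 read -4.08 on 1 array. Of 80 named genes tested 56 passed, 21 positive and 35 negative. All features past the threshold numbered 8972 of 15488 (4522 positive, 4450 negative), of which 4758 were at 1 log2 or more (2040 positive, 2718 negative). By layout 5617 of 9368 passed, and 5860 features did so without array 2 of this species (2774 positive, 3086 negative).

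Petunia showed GBSS at 3.15 log2 (SE 0.19, 8.86-fold, adjusted p = 4.75e-06), MS at 1.77 (SE 0.16, adjusted p = 3.68e-05), HXKRP1 at 1.54, AOX at 1.43, HPL at 1.24 and CAT1 at 1.21. A second CAT1 clone was negative at -1.33. The FLS clone near the rounding limit gave -6.14, against 1.42 for another FLS clone. MIP2 reached -4.27 (SE 0.17, 19.3-fold, adjusted p = 2.20e-06), NAC2 -3.37, SRE1A -2.64, PR1B -2.36 and PSBR -2.21. Of 83 named genes tested 56 passed, 17 positive and 39 negative. In all, 8925 of 15770 features passed (4467 positive, 4458 negative), 4775 of them at 1 log2 or more (2123 positive, 2652 negative). Layout averaging gave 5526 of 9504, and 5663 features passed without petunia array 2 (2715 positive, 2948 negative).

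**Figure D2:**
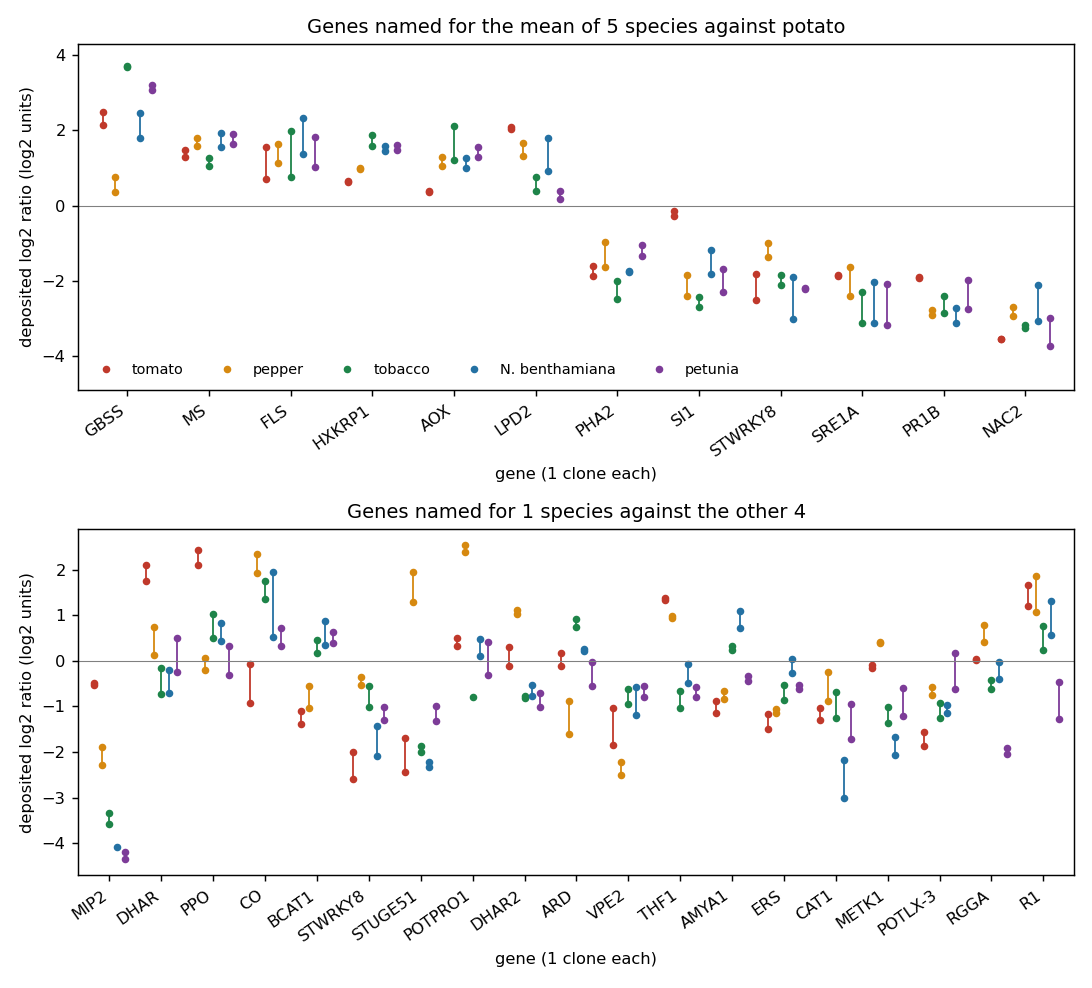
Deposited log2 ratios (vertical axis, log2 units) of genes named for the mean of 5 species (upper panel) and for 1 species against the other 4 (lower panel), 1 clone each; each point is 1 array, coloured by species, and lines join the 2 arrays of a species. In the upper panel GBSS lies above 0 and NAC2 below 0 on all 10 arrays; in the lower panel STUGE51 is positive only on the 2 pepper arrays.

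Named genes were also viewed by the fixed lists, to which they were assigned by protein name after their values had been seen, without a list test. Of the 3 starch genes, GBSS was past the threshold on the positive side in all 5 species, with pepper lowest at 0.56 log2, while another GBSS clone read -0.27 on its 1 pepper array. R1 was positive in tomato, pepper and Nicotiana benthamiana and, in 1 clone, negative in petunia, while the alpha-amylase gene AMYA1 was negative in tomato at -1.01 and pepper at -0.75 and positive in Nicotiana benthamiana at 0.91. Among 5 transcription factor genes, NAC2, STWRKY8 and BEL5 were negative and CO and MADS16 positive in the mean of 5 species; BEL5 stood at -1.28 (SE 0.085) in its clone with the smallest p, and another MADS16 clone was negative in 4 species. The infection marker PR1B was negative in all 5 species. In 1 clone PSBR was negative in all 5 species, from -1.29 to -2.21, but another PSBR clone stood at 0.70 in tomato. TK, of the Calvin cycle, was positive in all 5 species, from 0.97 to 1.74 in the same clone.

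Of the oxylipin genes, HPL was positive in tomato, pepper, Nicotiana benthamiana and petunia, with adjusted p-values down to 2.69e-05, and the lipoxygenase gene POTLX-3 was negative in tomato at -1.71, pepper, tobacco and Nicotiana benthamiana; its petunia value was -0.22 (adjusted p = 0.38). PPO, placed as a trichome marker, was positive in tomato, tobacco (0.76) and Nicotiana benthamiana (0.64). Cyclin genes CYCD3.2 and CYCD3.3, markers of dividing tissue, were both positive in tomato (0.98 and 1.86) and pepper (0.86 and 0.59). In tobacco CYCD3.2 was positive too at 1.02 (adjusted p = 0.0102), and CYCD3.3 stood at 0.17 (adjusted p = 0.437). On its 1 Nicotiana benthamiana array CYCD3.2 read 1.61. The ethylene receptor gene ERS was negative in 4 species, from -1.33 in tomato to -0.58 in petunia, and stood at -0.12 (adjusted p = 0.557) in Nicotiana benthamiana. Of the sucrose genes, the acid invertase gene PAIN-1 was negative in tomato (-1.61), tobacco (-1.31) and Nicotiana benthamiana (-1.84). The transporter gene SUT2 was tested in petunia alone and was positive there (0.90). The flavanone 3-hydroxylase gene F3H was positive in tomato at 1.78. Each other species had 1 array with a value and was not tested, from 0.19 in Nicotiana benthamiana to 1.71 in petunia. The photorespiration gene SHMT, a serine hydroxymethyltransferase, was tested in tobacco alone and stood at -0.56. CAT1, of the same list, was split between clones.

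Differences among the 5 species were found for 46 of 83 named genes by the moderated F test, and for 67 with the array number as a block. A gene counted here if any of its clones passed. By clone, 59 of 139 passed, and 103 with the block. Counts between species without the block ignore the pairing of arrays by potato RNA and tend to be too low. GBSS differed among species (adjusted p = 0.00134), from 0.56 in pepper to 3.70 in tobacco, and so did PPO (adjusted p = 0.00442), from -0.08 in pepper to 2.27 in tomato. NAC2 and PR1B, far on the negative side in every species, did not pass (adjusted p = 0.179 and 0.0993). With the block PR1B passed (adjusted p = 0.0153) and NAC2 did not (0.0976), and the same PR1B clone was 0.78 log2 more positive in tomato than in the other 4 (adjusted p = 0.0406). Over all features 4380 of 16899 passed (25.9%), and 8906 with the block. Without tomato array 1 or 2 the count was 1545 and 1515, without pepper array 1 2726 and without tobacco array 1 2770. Features past the threshold on opposite sides of potato in different species numbered 978.

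Tomato differed from the others in MIP2, which was 2.97 log2 more positive than the mean of the other 4 (SE 0.19, 7.81-fold, adjusted p = 1.49e-04), Nicotiana benthamiana having a value on 1 array. DHAR was more positive by 2.01 (SE 0.28, adjusted p = 2.33e-03) and PPO by 1.94 (SE 0.24, adjusted p = 1.34e-03), but another DHAR clone stood at -0.72 (adjusted p = 0.0953, and 0.0146 with the block). On the other side lay CO at -1.85, the branched-chain aminotransferase gene BCAT1 at -1.40 and STWRKY8 at -1.27, with a second STWRKY8 clone at -0.21 (adjusted p = 0.654). CO (adjusted p = 0.12) and BCAT1 (0.0635) missed the threshold without tomato array 1, and STWRKY8 (0.121) without tomato array 2. Of 83 named genes 36 passed, 23 more positive and 13 more negative in tomato, and 48 did so with the block. Features past the threshold numbered 3688 of 16899 (1782 more positive, 1906 more negative), and 6334 with the block. The balance turned at 1 log2 or more, with 976 more positive and 640 more negative of 1616, and with median-centring, with 1865 and 1767. The count was 545 without tomato array 1 (393 more positive, 152 more negative) and 583 without tomato array 2 (353 and 230), so the balance turned there too. Without petunia array 1 or 2 the sides were nearly even (1521 and 1508, 1589 and 1587).

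Pepper was set apart by STUGE51, 3.48 log2 more positive than the mean of the other 4 (SE 0.25, 11.1-fold, adjusted p = 4.19e-04), POTPRO1 at 2.47 (SE 0.23, adjusted p = 1.10e-03, tobacco on 1 array) and DHAR2, a dehydroascorbate reductase, at 1.62 (SE 0.18, adjusted p = 1.27e-03). GBSS lay on the other side at -2.27 log2 (SE 0.22, adjusted p = 8.22e-04), ARD, an acireductone dioxygenase of methionine salvage, at -1.44 and VPE2 at -1.42. The other VPE2 clone stood at 0.54 (adjusted p = 0.117). ARD and VPE2 had adjusted p-values of 0.0702 and 0.1 without pepper array 1. Of 83 named genes 24 passed, 14 more positive and 10 more negative, and 33 with the block. In all, 2018 features passed (1195 more positive, 823 more negative), 4015 with the block and 1078 at 1 log2 or more (686 of these more positive). The count was 429 and 667 without pepper array 1 or 2, and 1268 and 1232 without tomato array 1 or 2.

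Petunia had RGGA at -1.95 log2 relative to the mean of the other 4 (SE 0.18, 3.86-fold, adjusted p = 2.12e-03), R1 at -1.95 (SE 0.31, adjusted p = 1.25e-02) and MIP2 at -1.74 (SE 0.19, adjusted p = 4.10e-03, Nicotiana benthamiana on 1 array). GBSS was more positive by 0.97 (SE 0.22, adjusted p = 0.035) and POTLX-3 by 0.91 (SE 0.23, adjusted p = 0.048). GBSS and POTLX-3 missed the threshold when either petunia array, or any of several arrays of other species, was left out. With its spots kept separate, the POTLX-3 spot with the larger p gave 0.19 (adjusted p = 0.78). R1 missed it when either petunia array was left out (adjusted p = 0.0565 and 0.107), and MIP2 without petunia array 1 (0.0597). Of 83 named genes 12 passed, 2 more positive and 10 more negative, and 31 with the block. Features past the threshold numbered 1028 (428 more positive, 600 more negative), 3019 with the block and 563 at 1 log2 or more (226 more positive, 337 more negative). The count was 51 and 148 without petunia array 1 or 2, 412 and 403 without tomato array 1 or 2, 682 and 650 without those of pepper, and 523 and 480 without those of tobacco.

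For Nicotiana benthamiana, AMYA1 was 1.37 log2 more positive than the mean of the other 4 (SE 0.18, 2.59-fold, adjusted p = 8.34e-03) and ERS 0.81 (SE 0.18, adjusted p = 0.0477). CAT1 stood at -1.58 (SE 0.30, adjusted p = 0.0282), METK1, an S-adenosylmethionine synthetase, at -1.41 (SE 0.21, adjusted p = 0.0128) and MIP2 at -1.50 (SE 0.25, adjusted p = 0.0215). The MIP2 value rests on 1 array of this species, so it has no replicate here and the potato RNA does not cancel in it. A second CAT1 clone gave -0.24 (adjusted p = 0.524), and 7 other METK1 clones gave -0.31 to -0.99, none past the threshold (adjusted p from 0.0982 to 0.755) and 5 of them past it with the block. ERS missed the threshold under most alternatives, among them median-centring (adjusted p = 0.0518). Without array 2 of this species CAT1 (adjusted p = 0.175) and METK1 (0.0981) missed it, and CAT1 and MIP2 did so when either tomato array was left out, as did CAT1 without tobacco array 1 (0.0588). Of 83 named genes 8 passed, 2 more positive and 6 more negative, and 16 with the block. All features past the threshold numbered 565 (266 more positive, 299 more negative), 2143 with the block. The count was 194 and 73 without array 1 or 2 of this species (40 more positive, 33 more negative without array 2), 191 and 166 without those of tomato (85 and 81 without array 2), and between 265 and 353 without any 1 array of pepper, tobacco or petunia.

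In tobacco, GBSS was more positive than the mean of the other 4 by 1.66 log2 (SE 0.22, 3.17-fold, adjusted p = 0.0133), and THF1, a thylakoid formation gene, stood at -1.19 (SE 0.18, adjusted p = 0.0237); these were the only 2 of 83 named genes past the threshold, against 32 with the block. A second GBSS clone gave 0.27 (adjusted p = 0.504) and stood lower in tobacco (1.28) than in tomato (1.79) or petunia (1.73). Both missed it when either tobacco array was left out (GBSS adjusted p = 0.178 and 0.15, THF1 0.16 and 0.169). THF1 also missed it without tomato array 1 (0.0684), tomato array 2 (0.0687) or pepper array 1 (0.0508). Features past the threshold numbered 202 (109 more positive, 93 more negative) and 2118 with the block (1117 and 1001). The balance turned by layout, with 130 and 134 of 264 among 9976, and for features on all 10 arrays, with 161 and 174. Among the 5 counts of 1 species against the other 4, 202 was the smallest. With the block, however, the tobacco count was close to the 2143 of Nicotiana benthamiana. In limma 3289 features had an unadjusted p under 0.05 against 3190 there. Without tobacco array 1 limma called 0 of 16350 and without tobacco array 2 it called 0 of 15572, with 1825 and 2311 at an unadjusted p under 0.05, where 818 and 779 were expected by chance. It called 35 and 54 without tomato array 1 or 2, 76 and 104 without those of pepper, and 86 and 102 without those of petunia.

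**Figure D3:**
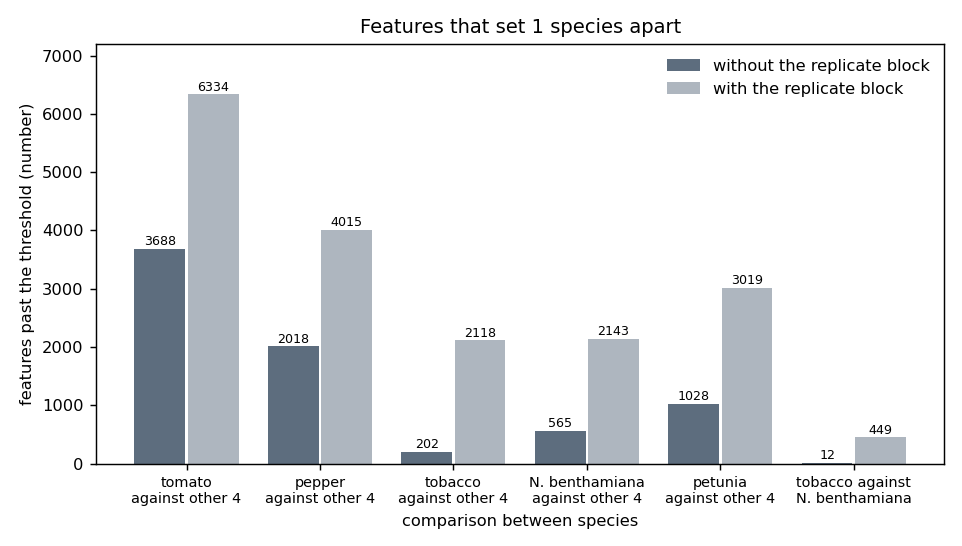
Number of features past the threshold (vertical axis, count) in each comparison between species (horizontal axis), without (dark bars) and with (light bars) the array number as a block. Counts without the block run from 12 for tobacco against Nicotiana benthamiana to 3688 for tomato against the other 4, and they are larger with the block in each comparison.

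Tobacco and Nicotiana benthamiana, the only pair from 1 genus among the 5 species other than potato, had few features past the threshold. With 2 arrays each, this does not show how many features differ. None of 86 named genes passed in limma: 0 were past the threshold and 20 had an unadjusted p under 0.05, the smallest adjusted p being 0.0713 for GBSS, 1.56 log2 more positive in tobacco. With the block 6 named genes passed, GBSS among them (adjusted p = 0.00584). Over all features 12 of 18061 passed, 8 more positive and 4 more negative in tobacco, and 1938 had an unadjusted p under 0.05. By layout these 12 were 9 clones. With the block the count was 449, of which 203 were more positive and 246 more negative, so the balance turned. With clones averaged by layout 18 passed, 9 more positive and 9 more negative. Leaving out tobacco array 1, tobacco array 2 or Nicotiana benthamiana array 2 gave 0, with 1425, 1489 and 1581 at an unadjusted p under 0.05; without Nicotiana benthamiana array 1 the count was 6, without either tomato array 4 and without either pepper array 3. The 4 more negative features, listed after their values had been seen and unnamed here, were spots 132748 (-3.69 log2), 155973 (-3.52), 137182 (-1.98) and 160416 (-1.82). Spots 132748 and 155973 had a value on 1 tobacco array only, so the potato RNA does not cancel in them. The 8 more positive features were a clone with several gene symbols (2.13) and spots 148406 (4.51), 135724 (3.46), 147562 (3.235), 133865 (3.10), 136232 (2.52), 135388 (2.16) and 159353 (1.71). They held 3 pairs of duplicate spots by layout. Spot 148406 read -6.643, the lowest value, on Nicotiana benthamiana array 2.

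Tomato had the narrowest distribution of log2 ratios against potato. The interquartile range over spots averaged 1.09 log2 in tomato, 1.22 in pepper, 1.28 in tobacco, 1.34 in Nicotiana benthamiana and 1.29 in petunia (n = 2 arrays each). The mean of the other 4 species was 1.18 times that of tomato, and the 8 ratios within an array number ran from 1.11 to 1.30. Tomato was lowest within both array numbers. Its 2 arrays against the 8 others gave a two-sided exact permutation p of 0.0444 over 45 splits, the smallest this design allows. Adjusted over the 5 species it was 0.222, but no species could have passed after adjustment, so the test does not decide. Array 2 of Nicotiana benthamiana had the widest range, 1.46.

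On average, profiles of the 2 arrays of a species correlated more than those of different species. Over 11569 features Pearson's r averaged 0.903 within species (0.874 to 0.942) and 0.768 between species (0.648 to 0.909), a gap of 0.135. The ranges overlapped: the 2 arrays of Nicotiana benthamiana correlated with each other at 0.874, and with the tobacco array of the same number at 0.906 and 0.909. Between species, arrays with the same number averaged 0.792 and arrays with different numbers 0.744. Tobacco with Nicotiana benthamiana averaged 0.875, tobacco with petunia 0.845 and Nicotiana benthamiana with petunia 0.825. Pepper correlated with these 3 species at 0.753 to 0.766, and tomato with the other 4 at 0.708 to 0.728. These correlations are across features, which are not independent replicates, and all arrays share potato RNA.

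**Figure D4:**
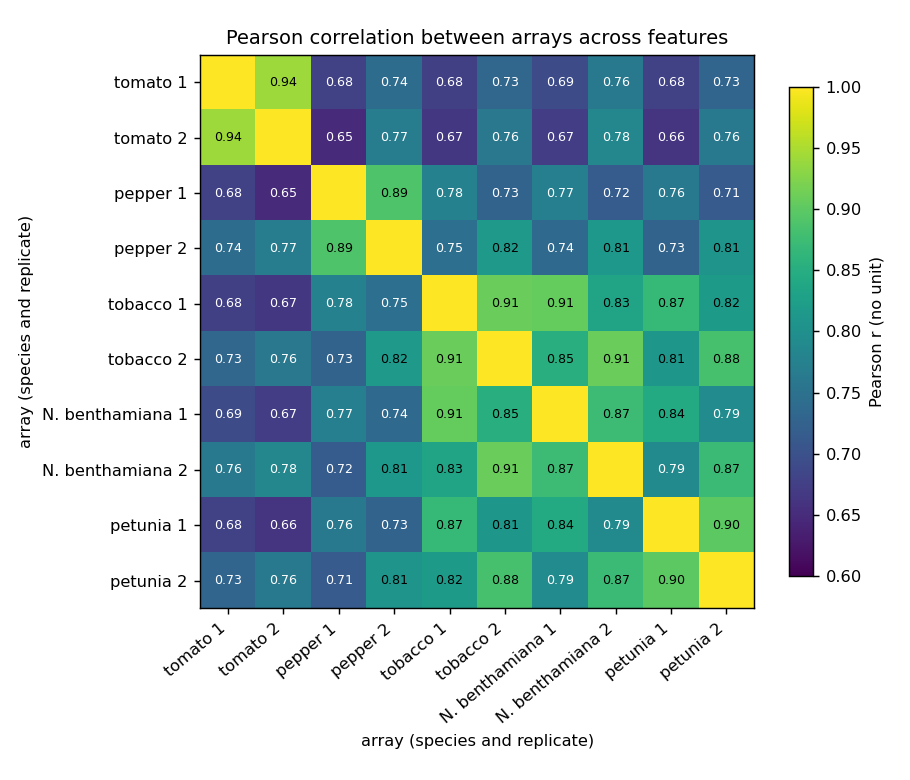
Pearson's r (colour scale and numbers, no unit) between each pair of the 10 arrays (both axes: species and array number) across 11569 features. Tobacco, Nicotiana benthamiana and petunia have the highest averages between species, although single pairs overlap (pepper array 2 with tobacco array 2 at 0.815, petunia array 1 with Nicotiana benthamiana array 2 at 0.790), and tomato with other species gives the lowest, down to 0.648.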

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

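The 8 pairs of species compared here, and the test for the number of arrays and spots behind a clone, were chosen only after the values had been seen; the other tests of explanations were set out before their results were seen.

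In 8 of the clones chosen by the rule for naming genes, 1 species was past the threshold on the positive side of potato and another on the negative side. Over all 157 clones with a gene name this held for 15 clones of 12 genes, and the clones not chosen by the rule, among them 1 each of METK1, PHA2, PEST2 and DD, were not tested for a difference. For the 8, the difference between the highest and the lowest species was computed with limma (n = 2 arrays each). Its adjusted p ran from 0.00113 to 0.00861, but clones and pairs were chosen for lying on opposite sides, which favours a pass and which these values do not take into account. STUGE51 stood at 1.62 log2 in pepper and -2.28 in Nicotiana benthamiana, a difference of 3.89 (SE 0.31); the other 3 species were negative too. RGGA stood at 0.60 in pepper and -1.98 in petunia, a difference of 2.58. R1 stood at 1.45 in pepper and -0.87 in petunia in 1 of its clones, a difference of 2.32, with an adjusted p of 0.0625 without pepper array 1 and 0.0532 without petunia array 2. THF1 stood at 1.36 in tomato and -0.85 in tobacco, a difference of 2.21. ARD stood at 0.83 in tobacco and -1.24 in pepper, a difference of 2.08. DHAR2 stood at 1.07 in pepper and -0.86 in petunia, a difference of 1.93. AMYA1 stood at 0.91 in Nicotiana benthamiana and -1.01 in tomato, a difference of 1.92. BCAT1 stood at 0.61 in Nicotiana benthamiana and -1.24 in tomato, a difference of 1.85.

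Each Nicotiana benthamiana array correlated more with the tobacco array of its own number (r = 0.906 for array 1 and 0.909 for array 2) than with the other array of its species (0.874). Exchanged labels of the arrays numbered 2 were argued against: with each array number centred per feature, the exchanged pairs correlated less than the labelled ones, by -0.419 in mean r. A shared array number, through the same potato RNA or the same processing, is a candidate explanation. After the centring, array 2 correlated with its own species more than with either tobacco array, by 0.402. Centring lowers correlations between species by construction, so this difference was partly built in and is weak support. Without centring, the r of array 2 with tobacco array 1, of the other number, was 0.834. Whether the potato RNA or the processing would be behind a number effect cannot be told apart, since each number has both. The close relation of the 2 species stays open as untested.

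Clones with a gene in the annotation lay more often on the negative side. In single species, 57.3% to 70.5% of the features with a gene past the threshold and 48.1% to 51.6% of those without were negative; among clones averaged by layout and past the threshold for the mean of 5 species, 65.4% (95% Wilson interval 61.4 to 69.2) of those with a gene and 48.5% of those without were negative. Measurement on more arrays or spots was argued against by a difference of 17.1 points among clones with both spots measured on all 10 arrays (69.3% and 52.2%). Position on the array was argued against by a share of 49.5% in unnamed clones weighted to the same positions. Repeated clones of few genes were argued against with each of 369 genes counted once by its median, past the threshold or not. Of these genes 61.8% (56.7 to 66.6) were negative, beside 48.9% of all tested clones without a gene. How the annotated clones were chosen, sequence conservation between species and the authors' normalisation stay open and may each contribute. No biological explanation was tested, since the groups give none.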

How the results depend on the processing

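Averaging clones by layout, the settings for differences between 2 species and those for the count common to all 5 species were chosen after the data were seen. Of 1815 alternatives for 104 results on named genes, 1755 kept direction and side of the threshold, 60 kept direction but missed it (53 of them by leaving out an array) and 0 turned direction; the block ended none of these calls. These 104 results had been chosen for passing the threshold, most of them as the largest ratios. The tally therefore does not describe typical calls. Over 1762 tests of clones with a gene name, called or not, 686 passed without the block and 909 with it. Among tests with a p-value in both fits, the block ended 0 calls and added 231. These tests include those against potato, where blocked p-values are too small, so added calls there are no support. Some calls had too few values for a p-value with the block. Counts under settings not given here stayed within 1.5 times, apart from further runs without 1 array, given with each count above. Leaving out an array leaves its species with 1 array, assumed to vary like the others, and fewer features tested. That species then carries 1 potato RNA, which does not cancel in comparisons between species. Other causes were not tested. Gene list tests and their 3 alternatives could not be run, for want of members. Signal over background was not analysed here.

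With a minimum of 1 log2, counts against potato were 4118 for tomato, 4033 for pepper, 4711 for tobacco, 4758 for N_benthamiana (Nicotiana benthamiana), 4775 for petunia and 2981 for the mean of 5 species. Against the other 4 they were 1616 for tomato, 1078 for pepper, 373 for N_benthamiana and 563 for petunia, and the F test gave 1140 at adjusted p under 0.01. Averaging by layout, which counts each clone once, gave 5164 for tomato, 5136 for pepper, 5569 for tobacco, 5617 for N_benthamiana and 5526 for petunia against potato. With the replicate block the F test gave 8906, tomato against the other 4 gave 6334, pepper 4015, tobacco 2118, N_benthamiana 2143, petunia 3019 and tobacco against N_benthamiana 449. Features on all 10 arrays gave 335 for tobacco against the other 4 and 43 for tobacco against N_benthamiana, robust moderation 33 and separate spots 35 for the latter. Scaling to the same median absolute deviation gave 325 for N_benthamiana against the other 4. Centring each array number moved the gap between correlations within and between species to 0.948, since it pushes those between species below 0 by construction.

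Leaving out 1 array at a time, counts against potato ran from 3706 (without tomato 2) to 8800 for tomato, 4895 (pepper 2) to 8426 for pepper, 5345 (tobacco 2) to 9227 for tobacco, 5860 (N_benthamiana 2) to 8874 for N_benthamiana and 5663 (petunia 2) to 9208 for petunia. The F test ran from 1515 (tomato 2) to 4546. Against the other 4, tomato ran from 545 (tomato 1) to 3880, pepper from 429 (pepper 1) to 2176, tobacco from 0 (either tobacco array; 1825 and 2311 at an unadjusted p under 0.05 in limma) to 283, N_benthamiana from 73 (N_benthamiana 2) to 353 and petunia from 51 (petunia 1) to 1050. Tobacco against N_benthamiana ran from 0 (tobacco 1, tobacco 2 or N_benthamiana 2; 1425, 1489 and 1581 at an unadjusted p under 0.05) to 18.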

Other observations

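Both tests on sequence divergence were set out before their results were seen; METK1, SI1 and the share for pepper were singled out only after their values had been seen.

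METK1, an S-adenosylmethionine synthetase gene, was negative in both Nicotiana species in every clone tested there, 8 of 8 in tobacco and 7 of 7 in Nicotiana benthamiana. Its clone with the smallest p stood at -1.19 log2 in tobacco (SE 0.19, adjusted p = 0.000639) and -1.86 in Nicotiana benthamiana, at -0.90 in petunia (adjusted p = 0.00289) and at 0.40 in pepper (adjusted p = 0.0995). In petunia 4 of 8 METK1 clones were past the threshold, all negative. In tomato 1 of 6 passed, at -0.67, and in pepper 1 of 9, on the positive side at 0.57. SI1 was negative in pepper, tobacco, Nicotiana benthamiana and petunia in all 3 of its clones, while its tomato values were -0.22, -0.21 and 0.03, none past the threshold. Against the other 4 species, the 3 SI1 clones were more positive in tomato by 1.82 (adjusted p = 0.00214), 1.38 (0.00593) and 1.48 log2 (0.00582). Whether transcript level or binding to the clones lies behind the METK1 and SI1 values was not tested.

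Values on both arrays of 1 species and on no array of another were found for 53 spots in tomato, 8 in pepper, 12 in tobacco, 4 in Nicotiana benthamiana and 11 in petunia. Spots missing on both arrays of 1 species and present on all 8 others numbered 8 in tomato, 66 in pepper, 22 in tobacco, 19 in Nicotiana benthamiana and 41 in petunia. The rule that left a spot without a value is not given in the sources used here, so these counts do not show presence or absence of a transcript.

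Diverged sequences might bind the spotted clones less well in distant species. If so, clones near 0 in tomato (within 0.5 log2) and far from 0 (at least 1 log2) in the other 4 species would lie mostly on 1 side. For tomato 204 of 434 were negative, 47.0% (95% Wilson interval 42.4 to 51.7), and the share differed from that for petunia by 4.74 points. Clones near 0 in pepper and far from 0 in the others leaned to the negative side, 113 of 193 or 58.5% (51.5 to 65.3). As the direction of the ratio was not settled and both sides were filled in tomato, the test neither excludes nor favours such binding.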
